A study of Homo sapiens with 12 samples.

How the data were processed

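Total RNA of SUM-149 cells was hybridised to Illumina HumanHT-12 version 3 BeadChips, 1 array per sample, as biotin-labelled cRNA per the labels. The 4 groups of 3 arrays were the parental cells, the cells with a non-silencing vector (shNS), the cells with a single AREG shRNA virus (sh4) and the cells with 3 AREG shRNA viruses (shPld), as the sample titles give them. The labels do not say whether the virus of sh4 is among the viruses of shPld. The 3 infected lines were grown with puromycin, per the labels' protocols, and the parental cells without it.

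The deposited non-normalized table holds average bead signal intensity per probe on a linear scale, with its background, per the file headers. It has no detection p-values and no negative controls, and the scanner software is not given in the sources used here. The deposited value table holds log2 intensity. Its scale is known from a comparison with the non-normalized signals: each column is the log2 signal after quantile normalization without background correction, the sorted values of the first column lying within 0.0025 of the mean sorted log2 signal, and the median of each column is 6.84. The remaining deposited table holds the authors' group means of these log2 values with a gene symbol and an accession per probe, and its group means were not used in the comparisons. The non-normalized table names probes by array address, the others by probe ID. The rows were joined by their values: each of the 48803 rows was matched to the nearest probe over the 12 arrays after quantile normalization, 48803 matched one to one, the largest distance to a match was 0.0017 and the smallest distance to the next probe 0.0838 (log2).

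Genes were named through the accession in the deposited table and a RefSeq gene table without a named assembly (26251 probes), by current symbol (2023) or older symbol (993), or kept the deposited symbol (6883), and 12653 probes stayed without a name, 50 of them with symbols turned into dates. The 36150 named probes stand for 24978 genes.

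The planned background correction needs detection p-values. In their place, the mean background of each array was read from the mode of its signals (101.8 to 109.1) and its SD from the spread below the mode (10.1 to 11.2). The correction therefore departs from the planned one. Limma's normexp model with these values and an offset of 16, log2 and quantile normalization then gave the values that were tested. A probe counted as above background where its signal had an upper-tail p under 0.05 in that background (a signal of at least 118.6 to 126.8). Probes above background on all 3 arrays of at least 1 group were kept (17763), and the probe with the highest mean stood for each gene (12594 genes, of which 2998 had several kept probes), while 1370 kept probes had no name. For ERBB3, another kept probe passed in the opposite direction in shPld minus shNS, so ERBB3 is given no value.

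All 4 groups entered 1 linear model per gene (limma 3.58.1 in R 4.3.3, lmFit and eBayes with an intensity trend, 8 residual and 18.5 prior degrees of freedom, two-sided, Benjamini-Hochberg over 12594 genes, adjusted p under 0.05). The comparisons were sh4 and shPld minus shNS, shNS minus parental, and shPld minus sh4. A gene above background on 0 arrays of a group is given as at least N-fold, from the brighter group's mean to the dimmer group's mean of, per array, the higher of the lowest signal above background and the gene's own. Gene lists were tested with camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over 20 lists per comparison), and with an estimated correlation, which kept 8 of 8 calls in sh4 minus shNS, 9 of 11 in shPld minus shNS, 10 of 10 in shNS minus parental and 1 of 1 in shPld minus sh4.

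These choices were made before the data were examined: the groups, the tests, the alternatives, the 20 gene lists (460 genes) and the rule for named genes. Per comparison the rule took AREG, the 8 highest and 8 lowest log2 fold changes past the threshold with non-overlapping arrays, the 8 highest and 8 lowest of the genes changed the same way in both lines by the smaller of their changes, up to 4 members of each list past the threshold with the largest changes (where fewer than 2 passed, also the 2 brightest members), and always EGFR, EREG, HBEGF, TGFA, IL1A, IL1B, CXCL8 and IL6. The report names part of the genes that the rule took. A gene named for 1 shRNA line against shNS is given for both. The lists were the EGFR family and its ligands, ERK pathway targets, NF-kappaB and inflammatory cytokine genes, interferon-stimulated genes, proteases of invasion and their inhibitors, integrins and basement membrane, epithelial junction, mesenchymal, keratinocyte differentiation, basal epithelial, luminal epithelial (EGFR stands in 2 lists), DNA replication, mitosis, p53 targets, cholesterol synthesis, ATF4 and unfolded protein response, hypoxia and glycolysis, antigen presentation, microRNA processing, and markers of leukocytes, endothelium and fibroblasts.

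The fit and the calls were checked on simulated values made from the real means and spreads after normalization, with genes drawn independently. Background correction, normalization and filtering were not part of this check. For sh4 minus shNS, with 200 of 12594 genes changed, the fit recovered 25.8% of genes changed by 0.5, 76.1% of those changed by 1 and 100% of those changed by 2 on the log2 scale, with 2 false calls. Alternatives covered the background correction, median scaling, the authors' log2 values, no filter and a stricter one (above background at 0.01 on all 12 arrays), the replicate number as a block, each array left out, fits with only the compared groups, every probe, other thresholds, array weights, no trend, parental cells as control and separate controls. Chosen after seeing the data were limma's own normexp with an offset of 50 and the gene lists and named genes with parental cells as control. A total of 100 simulated sets of unchanged groups gave the values for shared controls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.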

Results

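SUM-149 is a human cell line from a triple negative inflammatory breast carcinoma. AREG encodes amphiregulin, a secreted ligand of the epidermal growth factor receptor (EGFR). Genome-wide expression was measured in the uninfected cells (parental), in cells carrying a non-silencing shRNA vector (shNS), in cells carrying a single AREG shRNA virus (sh4) and in cells that received 3 AREG shRNA viruses (shPld), with 3 arrays in each of the 4 groups. The comparison addressed which genes changed when AREG was targeted by shRNA. Mean signal per array lay between 438.4 and 545.8, and between 37.5% and 41.6% of the 48803 probes were above background. In all, 12594 named genes were tested. The labels do not say that the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Their number, 3 per group, limits the precision, and the median SE of a log2 difference was 0.148.

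The targeted gene was not measurable. The only AREG probe (ILMN_1804421) was above background on 0 of 3 arrays in each group, with a mean signal of 106.5 ± 2.4 in parental, 98.2 ± 7.6 in shNS, 95.8 ± 11.8 in sh4 and 96.8 ± 3.3 in shPld cells (SD, n = 3 each). The probe was at background in the uninfected cells as well, so it does not check the labels, and no fold change of AREG is read from it.

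Against shNS, the sh4 cells had higher ACKR3, a scavenging chemokine receptor, by 4.66 ± 0.16 on the log2 scale (SE; n = 3 arrays per group, as for all values here), and higher FLRT3, an adhesion molecule, by 4.17 ± 0.13. PLPP3, a lipid phosphate phosphatase, rose by 3.93 ± 0.15, the calcium-binding S100A8 by 3.62 ± 0.18, the G protein regulator RGS2 by 3.37 ± 0.07 and the membrane protein STOM by 3.23 ± 0.14. The lowest values were HLA-DRA, the alpha chain of HLA-DR, at -3.57 ± 0.14, the cytokine IL24 at -2.98 ± 0.09 and PHLDA1, a target of growth factor signalling, at -2.93 ± 0.08. SVEP1 rose by 3.72 ± 0.20 and was above background on 2 of 3 shNS arrays. CDKN1C, an inhibitor of cyclin-dependent kinases, was at least 10.2-fold higher and ZNF385B at least 6.90-fold higher, both being above background on 0 of 3 shNS arrays. In total 3414 genes passed an adjusted p of 0.05 in limma, 1603 higher and 1811 lower, of which 279 and 202 changed at least 2-fold. The 3 arrays of one group lay wholly outside those of the other for 4862 genes (38.6%), where chance gives 10%.

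The shPld cells showed the same leading genes against shNS: ACKR3 rose by 4.58 ± 0.16, FLRT3 by 4.14 ± 0.13, PLPP3 by 3.71 ± 0.15, STOM by 3.66 ± 0.14, S100A8 by 3.49 ± 0.18, SVEP1 by 3.40 ± 0.20 and RGS2 by 3.38 ± 0.07. CDKN1C was at least 9.56-fold and ZNF385B at least 6.58-fold higher. HLA-DRA was at -3.07 ± 0.14, PHLDA1 at -2.90 ± 0.08 and IL24 at -2.24 ± 0.09. NT5E, the ecto-5'-nucleotidase CD73, was at -2.38 ± 0.22 in shPld and -1.95 ± 0.22 in sh4 cells and was above background on 2 of 3 arrays in both. NTSR1, a neurotensin receptor, was above background on 0 of 3 arrays of either line, at least 4.06-fold lower in sh4 and at least 4.21-fold lower in shPld cells. In total 3242 genes passed, 1528 higher and 1714 lower, with 285 and 197 changed at least 2-fold, and 4913 genes (39.0%) had non-overlapping arrays against the 10% of chance.

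Genes that changed the same way in both lines numbered 2299, 1077 higher and 1222 lower, while 5 passed in opposite directions. These were ATXN2, DBT, ITPRIPL2, NFKB1 and SERPINA3, named after their values were seen, and each lost its call in at least 1 line under some other setting. The 2299 genes made up 67.3% of the sh4 calls and 70.9% of the shPld calls. Independent lists of these lengths would share 194 higher and 246 lower genes. Simulated unchanged groups set against a common simulated control shared 0. In these sets no gene was changed and genes were drawn independently, so few calls could arise. The 0 therefore does not show how many of the 2299 genes the shared shNS arrays bring. Across genes, which are not independent replicates, the 2 sets of log2 fold changes correlated at r = 0.86, where simulated unchanged groups gave 0.50. The covariance was 0.184 against a simulated 0.0182, a difference of 0.166. The arrays used as control were shared, so the lines were also set against separate controls: sh4 against shNS and shPld against parental shared 829 higher and 981 lower genes (r = 0.68), and the reverse choice shared 906 and 1091 (r = 0.74). Scaling each array to a common median in place of quantile normalization gave a median of all genes of -0.175 in sh4 minus shNS and of -0.058 in shPld minus shNS, against -0.016 in both as reported. With it, 530 higher and 1231 lower genes were shared, and 19.2% of the sh4 calls were higher, against 47.0% as reported, and 38.2% of the shPld calls against 47.1%.

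**Figure D1:**
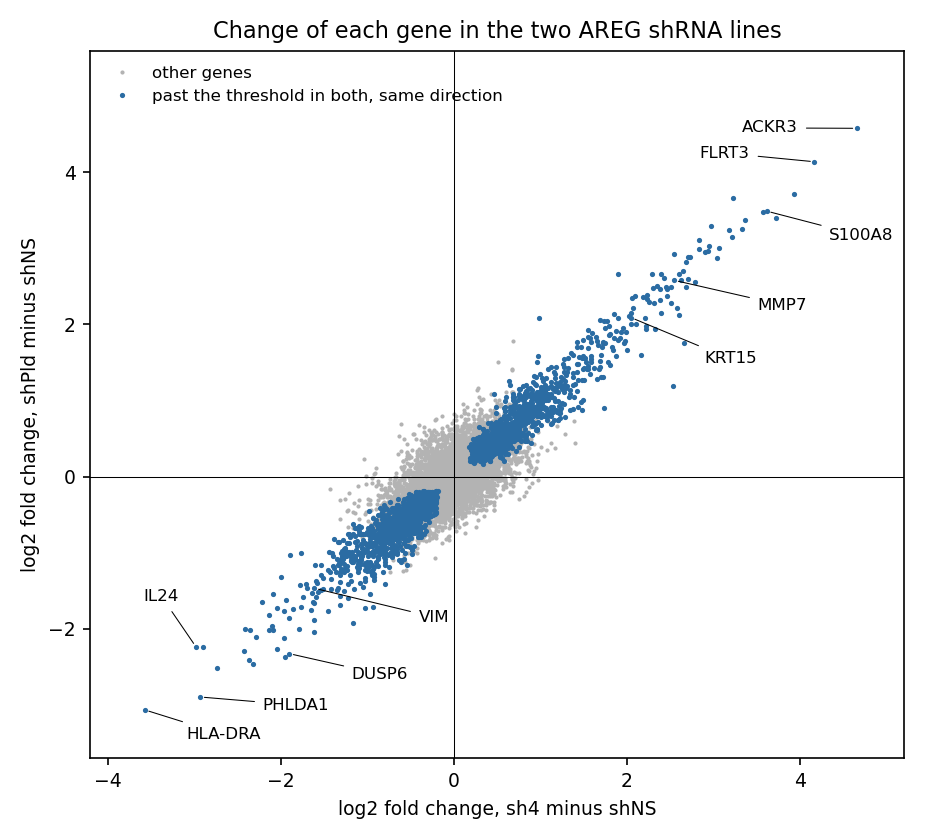
Each point is 1 of 12594 genes, with the log2 fold change of sh4 minus shNS on the horizontal axis and of shPld minus shNS on the vertical axis. Blue points are the 2299 genes past the threshold in both lines with the same direction, and ACKR3 lies at 4.66 and 4.58 and HLA-DRA at -3.57 and -3.07.

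Target genes of the ERK pathway, which relays signals from growth factor receptors, fell in both lines. Of 18 measured, 15 fell and 0 rose in sh4 cells, and 16 fell and 1 rose in shPld cells, the same numbers as when adjusted over the list alone. The medians were -1.31 and -1.02, with camera adjusted p of 9.5e-15 and 2.4e-15. PHLDA1 led the list. SPRY4 and SPRY1, feedback inhibitors of the pathway, were at -2.35 ± 0.23 and -1.94 ± 0.22 in sh4 cells and at -2.02 ± 0.23 and -1.62 ± 0.22 in shPld cells. The ERK phosphatase DUSP6 was at -1.90 ± 0.26 and -2.33 ± 0.26, and DUSP5 at -1.61 ± 0.16 and -2.05 ± 0.16. SPRY4 and SPRY1 were above background on 2 of 3 sh4 arrays, and DUSP6 on 2 of 3 sh4 and 1 of 3 shPld arrays.

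The EGFR ligands EREG and TGFA were lower. EREG (epiregulin) was at -2.14 ± 0.26 in sh4 and -1.82 ± 0.26 in shPld cells, above background on 2 of 3 arrays of each, and TGFA at -1.58 ± 0.18 and -1.40 ± 0.18. HBEGF was at -0.99 ± 0.21 in shPld cells and at -0.49 ± 0.21 in sh4 cells, where of 12 settings against shNS it passed only with median scaling (-0.63, adjusted p = 0.029; 0.029 to 0.38 over the 12). EGFR itself was at -0.27 ± 0.07 and -0.43 ± 0.07. A dimmer EGFR probe (ILMN_1696521) showed no fall in sh4 cells, with mean log2 levels of 6.49 in shNS, 6.54 in sh4 and 5.95 in shPld cells. The related receptor ERBB2 was at 0.72 ± 0.11 and 0.34 ± 0.11, the shPld call of ERBB2 being lost with median scaling (0.27) and without shPld replicate 1 (0.30), shPld replicate 2 (0.32), shNS replicate 2 (0.33) or shNS replicate 3 (0.34), with an adjusted p of 0.017 to 0.29 over 12 settings. Of the 9 members of the EGFR family list that were measured, 2 rose and 3 fell in sh4 cells (2 and 5 adjusted over the list alone) and 1 rose and 5 fell in shPld cells (2 and 5 adjusted over the list alone). The 5 that fell in shPld cells include ERBB3, for which another kept probe passed in the opposite direction. ERBB3 also took part in the list's test. The list's shift did not pass in sh4 cells (median -0.37, adjusted p = 0.14), but did with parental cells as control (-0.44, adjusted p = 0.047, and 0.087 with an estimated correlation), with 0.097 to 0.48 over 12 settings against shNS. It passed in shPld cells (median -0.43, adjusted p = 0.024), but not with an estimated correlation (adjusted p = 0.062) or with the strict filter (adjusted p = 0.14; 0.0064 to 0.14 over 12 settings).

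DNA replication genes fell together: of 25 measured, 20 fell and 0 rose in sh4 cells and 19 fell and 0 rose in shPld cells (20 and 21 fell adjusted over the list alone). The medians were -0.50 and -0.62, with adjusted p of 5.4e-11 and 2.9e-13. The replication clamp PCNA was at -1.07 ± 0.09 and -0.75 ± 0.09, the initiation factor MCM10 at -1.03 ± 0.13 and -0.96 ± 0.13, and GINS2, part of the replicative helicase, at -0.95 ± 0.08 and -0.68 ± 0.08. Mitosis genes moved less against shNS. Of 26 measured, 2 rose and 5 fell in sh4 cells (3 and 7 adjusted over the list alone; median -0.07, adjusted p = 0.75), and 1 rose and 8 fell in shPld cells (1 and 8 adjusted over the list alone; median -0.18, adjusted p = 0.0011). The mitotic kinase AURKB was at -0.30 ± 0.08 in sh4 and -0.52 ± 0.08 in shPld cells, its sh4 call being lost without sh4 replicate 1 (-0.25) or shNS replicate 1 (-0.22), with an adjusted p of 0.0011 to 0.085 over 12 settings. The mitotic transcription factor FOXM1 was at -0.59 ± 0.13 in shPld cells, and at -0.22 ± 0.13 in sh4 cells, where it did not pass. The centromere protein gene CENPF rose by 0.50 ± 0.10 in sh4 cells and was at 0.10 ± 0.10 in shPld cells, where it did not pass. The cyclin CCNB1 rose by 0.49 ± 0.10 and 0.40 ± 0.10. The calls of both genes were lost with median scaling: CENPF was at 0.28 in sh4 cells, and CCNB1 at 0.29 and 0.33. Against parental cells, mitosis genes had medians of -0.21 in sh4 (9 of 26 fell, adjusted p = 0.0051) and -0.41 in shPld cells (17 of 26 fell, adjusted p = 5e-07). Replication genes had -0.48 (18 of 25 fell) and -0.57 (17 of 25 fell). Over 12 settings against shNS the sh4 adjusted p of the mitosis genes was 0.21 to 0.83.

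Basal and luminal epithelial genes rose in the same cultures. The arrays measured whole cultures, so they do not show whether single cells expressed both. Of 15 basal genes, 10 rose in each line, while 2 fell in sh4 and 3 in shPld cells (10 and 11 rose, 2 and 3 fell, adjusted over the list alone). The medians were 0.80 and 0.89, or 0.69 and 0.74 with genes below background at their bound, and the adjusted p 7.5e-11 and 3.9e-09. MME (neprilysin, CD10) rose by 3.04 ± 0.14 and 2.87 ± 0.14. Among keratins of this list, KRT5 rose by 2.71 ± 0.08 and 2.60 ± 0.08, KRT16 by 2.43 ± 0.09 and 2.61 ± 0.09, and KRT15 by 2.05 ± 0.14 and 2.09 ± 0.14. Of 14 luminal genes, 7 rose in each line, while 1 fell in sh4 and 2 in shPld cells (8 rose and 2 fell in each adjusted over the list alone; medians 0.76 and 0.82, adjusted p of 6.2e-07 and 4e-07). KRT19 rose by 2.45 ± 0.10 and 2.49 ± 0.10, the transcription factor GATA3 by 2.05 ± 0.21 and 2.01 ± 0.21, and the mucin MUC1 by 1.96 ± 0.09 in both. CD24, a surface glycoprotein, rose by 1.98 ± 0.07 and 1.78 ± 0.07. Of 9 keratinocyte differentiation genes, 5 rose and 0 fell in each line, also when adjusted over the list alone (medians 0.32 and 0.48, adjusted p of 0.00065 and 0.00021). Besides S100A8, its partner S100A9 rose by 1.38 ± 0.15 and 1.31 ± 0.15, and the elastase inhibitor PI3 by 0.92 ± 0.09 and 0.90 ± 0.09.

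**Figure D2:**
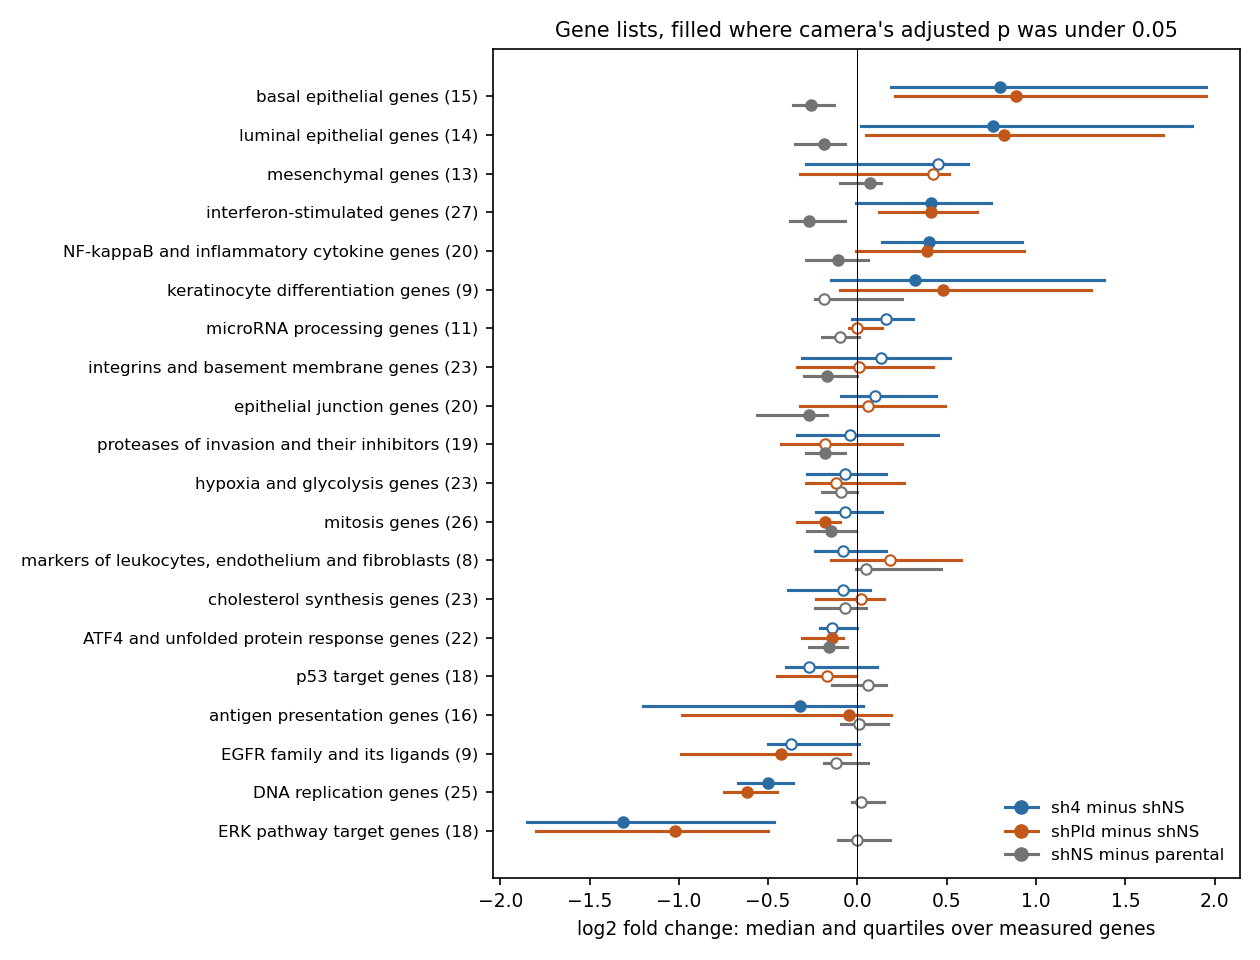
Median log2 fold change (points) and quartiles (lines) over the measured members of 20 gene lists, whose number stands in brackets, for 3 comparisons. Points are filled where camera's adjusted p was under 0.05, and ERK pathway targets lie lowest (medians -1.31 and -1.02) against shNS.

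NF-kappaB and inflammatory cytokine genes moved both ways. Of 20 measured, 11 rose and 3 fell in sh4 cells (14 and 3 adjusted over the list alone), and 9 rose and 4 fell in shPld cells (11 and 4 adjusted over the list alone). The medians were 0.40 and 0.39, with adjusted p of 2e-04 and 0.00034. TNFAIP2, a TNF-induced gene, rose by 2.32 ± 0.20 and 2.28 ± 0.20, and the neutrophil-attracting chemokines CXCL2 by 1.55 ± 0.13 and 1.83 ± 0.13 and CXCL1 by 1.27 ± 0.11 and 1.20 ± 0.11. IRAK2, a kinase of interleukin-1 signalling, was at -1.53 ± 0.26 and -1.30 ± 0.26, above background on 1 of 3 arrays of each line. IL1A rose by 0.43 ± 0.07 and 0.40 ± 0.07, and its sh4 call was lost with median scaling (0.23, adjusted p = 0.18; 3.9e-05 to 0.18 over 12 settings). Log2 differences that did not pass were 0.26 ± 0.12 and 0.23 ± 0.12 for IL1B, 0.48 ± 0.18 and 0.29 ± 0.18 for IL6, and 0.18 ± 0.09 and 0.20 ± 0.09 for CXCL8. A dimmer CXCL8 probe (ILMN_1666733), above background on 3 of 3 arrays in each group, differed more. Its mean log2 levels were 8.3 ± 0.18 in shNS, 8.79 ± 0.11 in sh4 and 8.76 ± 0.09 in shPld cells (SD), and 8.64 ± 0.04 in parental cells. The sh4 value of IL6 passed in 5 of 12 other settings, among them the leaving out of shNS replicate 1 (0.65, adjusted p = 0.017; 0.017 to 0.33 over the 12).

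Interferon-stimulated genes rose against shNS. Of 27 measured, 12 rose and 2 fell in sh4 cells (13 and 2 adjusted over the list alone), and 13 rose and 0 fell in shPld cells (14 and 2 adjusted over the list alone). The median was 0.41 in both, with adjusted p of 0.00025 and 1.9e-05. The chemokine CXCL10 rose by 1.55 ± 0.22 and 1.93 ± 0.22, IFI27 by 0.99 ± 0.26 and 2.09 ± 0.26, IFI44L by 1.07 ± 0.08 and 1.17 ± 0.08, and the antiviral GTPase MX1 by 1.23 ± 0.18 and 0.77 ± 0.18. CXCL10 and IFI27 were above background on 2 of 3 shNS arrays. The shift was smaller against parental cells, with medians of 0.07 for sh4 (adjusted p = 0.13) and 0.16 for shPld cells (adjusted p = 0.049, and 0.069 with an estimated correlation).

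Among antigen presentation genes, HLA-DRA, HLA-DRB1, HLA-DMA, HLA-DMB and CD74 of HLA class II fell in both lines. The class II genes are a part of the list set apart after its values were seen, and this part was not tested as a set. HLA-DMB, which helps load peptides, was at -2.41 ± 0.18 in sh4 and -2.0 ± 0.18 in shPld cells, and the invariant chain CD74 at -2.0 ± 0.22 and -1.32 ± 0.22. HLA-DRB1 was above background on 0 of 3 arrays in either line, at least 3.34-fold and 3.46-fold lower. HLA-DRB1 shares near-identical copies with HLA-DRB4 (-2.37 ± 0.21 and -2.41 ± 0.21) and HLA-DRB6 (-2.90 ± 0.25 and -2.24 ± 0.25), so these values are not separate measurements. HLA-DRB6 was above background on 1 of 3 sh4 and 2 of 3 shPld arrays, and HLA-DRB4 on 2 of 3 shPld arrays. Of 16 members of the whole list, 7 fell in each line, while 1 rose in sh4 and 3 in shPld cells (7 fell in each, 3 and 4 rose, adjusted over the list alone). The medians were -0.32 and -0.05, or -0.26 and -0.05 with genes below background at their bound, and the adjusted p 0.0029 and 0.038. The shPld call was lost with an estimated correlation (adjusted p = 0.081), without shNS replicate 2 (median -0.05, adjusted p = 0.073) and with the strict filter (adjusted p = 0.49), the range over 12 settings being 0.0025 to 0.49. The sh4 call was lost with the strict filter (median -0.17, adjusted p = 0.14), which leaves out genes that fell below background.

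**Figure D3:**
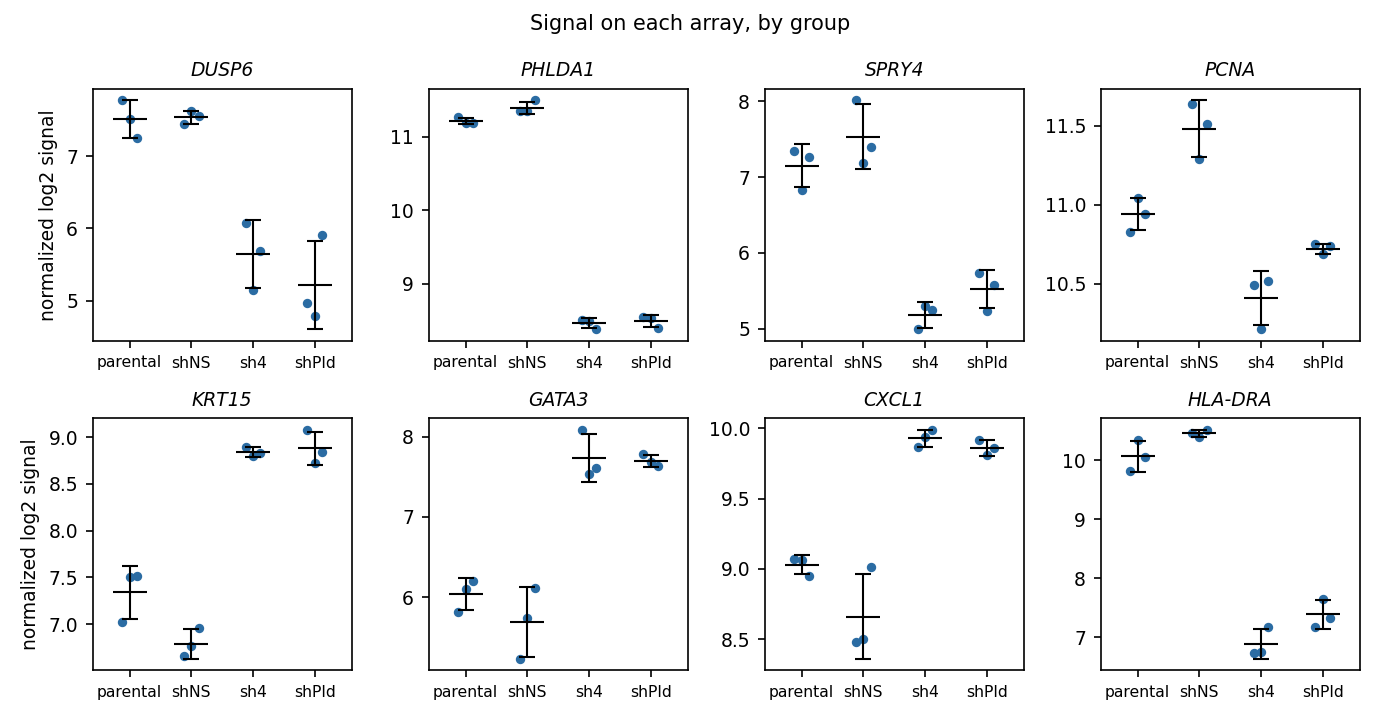
Normalized log2 signal of 8 genes on each array (points), with the mean and SD of each group (bars, n = 3). The axes differ in range and do not start at 0, and in each panel the 3 arrays of sh4 and of shPld lie apart from the 6 arrays of parental and shNS cells, as for HLA-DRA with means of 10.07 in parental, 10.46 in shNS, 6.89 in sh4 and 7.39 in shPld cells.

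Genes of invasion, adhesion and mesenchymal state changed in both directions. Of 19 measured proteases and inhibitors, 6 rose and 5 fell in sh4 cells (6 and 6 adjusted over the list alone) and 5 rose and 5 fell in shPld cells (5 and 6 adjusted over the list alone). The list did not shift (medians -0.04 and -0.18, adjusted p = 0.70 and 0.98), and in sh4 cells its median and its mean of 0.01 differed in sign. The matrix metalloproteinase MMP7 rose by 2.55 ± 0.10 and 2.58 ± 0.10 and the inhibitor TIMP2 by 1.02 ± 0.14 and 0.82 ± 0.14. MMP9 was above background on 0 of 3 arrays of either line, at least 2.07-fold and 2.14-fold lower, and the plasminogen activator PLAT was at -1.32 ± 0.23 and -1.69 ± 0.23. Of 23 integrin and basement membrane genes, 8 rose and 6 fell in sh4 cells (8 and 7 adjusted over the list alone; median 0.13, adjusted p = 0.14, and 0.049 without a filter, with 0.049 to 0.18 over 12 settings), and 7 rose and 5 fell in shPld cells (8 and 7 adjusted over the list alone; median 0.01, adjusted p = 0.40). ITGB4, the integrin beta 4 subunit, was at least 5.76-fold and 5.59-fold higher, with 0 of 3 shNS arrays above background, while its partner ITGA6 was at -1.20 ± 0.20 and -1.29 ± 0.20. Of 20 epithelial junction genes, 7 rose and 3 fell in sh4 cells and 6 rose and 4 fell in shPld cells, the same numbers as when adjusted over the list alone (medians 0.10 and 0.06, adjusted p = 0.14 and 0.36). Without a filter the junction genes passed in sh4 cells (adjusted p = 0.049; 0.049 to 0.18 over 12 settings). The desmosomal DSP rose by 1.19 ± 0.10 and 1.18 ± 0.10, and the claudin CLDN7 was at -0.68 ± 0.09 and -0.69 ± 0.09. Of 13 mesenchymal genes, 7 rose in each line, while 5 fell in sh4 and 4 in shPld cells (8 rose and 5 fell in each adjusted over the list alone; medians 0.45 and 0.42, adjusted p = 0.16 and 0.30). With parental cells as control they passed in sh4 cells (0.48, adjusted p = 0.022), though not with an estimated correlation (adjusted p = 0.052), with 0.14 to 0.60 over 12 settings against shNS. The transcription factor SNAI2 rose by 1.70 ± 0.09 and 1.60 ± 0.09, whereas VIM, encoding vimentin, was at -1.61 ± 0.08 and -1.47 ± 0.08.

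The p53 target genes did not pass as a list: of 18, 2 rose and 5 fell in sh4 cells and 3 rose and 4 fell in shPld cells, also when adjusted over the list alone (medians -0.27 and -0.17, adjusted p = 0.14 and 0.21). Without a filter the list passed in sh4 cells (-0.24, adjusted p = 0.037; 0.037 to 0.21 over 12 settings), and with genes below background at their bound the medians were -0.07 and -0.15. The cell cycle inhibitor CDKN1A was at -1.08 ± 0.10 and -1.01 ± 0.10. Of 23 cholesterol synthesis genes, 2 rose and 6 fell in sh4 cells (3 and 6 adjusted over the list alone) and 1 rose and 6 fell in shPld cells (1 and 6 adjusted over the list alone). The adjusted p were 0.11 (0.029 with median scaling and 0.026 without a filter, with 0.026 to 0.14 over 12 settings against shNS, and 0.019 with parental cells as control) and 0.36, with medians of -0.08 and 0.02, and the shPld mean of -0.15 differed from its median in sign. INSIG1, a sterol-sensing regulator of the pathway, was at -1.16 ± 0.11 and -1.13 ± 0.11. Of 22 ATF4 and unfolded protein response genes, 2 rose and 5 fell in sh4 cells (2 and 5 adjusted over the list alone; median -0.14, adjusted p = 0.084, 0.017 without a filter and 0.049 without shNS replicate 3, with 0.017 to 0.13 over 12 settings against shNS), and 1 rose and 6 fell in shPld cells (1 and 7 adjusted over the list alone; median -0.14, adjusted p = 0.017). The shPld call was lost with median scaling (-0.19, adjusted p = 0.17; 0.0029 to 0.17 over 12 settings). With parental cells as control the ATF4 medians were -0.29 and -0.33 (adjusted p of 3.3e-05 and 2.4e-05), and 13 of 22 fell in each line. The pseudokinase TRIB3 was at -0.68 ± 0.07 and -0.54 ± 0.07. Of 23 hypoxia and glycolysis genes, 5 rose and 5 fell in sh4 cells (5 and 5 adjusted over the list alone) and 5 rose and 6 fell in shPld cells (7 and 7 adjusted over the list alone). Their medians were -0.07 and -0.12 and their adjusted p 0.78 and 0.82, with tests of the opposite sign. NDRG1 rose by 0.99 ± 0.09 and 1.07 ± 0.09 and ENO2, a glycolytic enolase, was at -1.0 ± 0.18 and -0.73 ± 0.18. Of 11 microRNA processing genes, 2 rose and 0 fell in sh4 cells (0 and 0 adjusted over the list alone) and 1 rose and 0 fell in shPld cells (1 and 0 adjusted over the list alone), with medians of 0.16 and 0.00 and adjusted p of 0.30 and 0.77. Markers of leukocytes, endothelium and fibroblasts did not shift: of 8 measured, 1 rose and 1 fell in sh4 and 2 rose and 1 fell in shPld cells, also when adjusted over the list alone (medians -0.08 and 0.18, adjusted p = 0.70 and 0.21; the sh4 mean of 0.13 differed from its median in sign). The proteoglycan DCN rose by 2.30 ± 0.07 and 2.48 ± 0.07, and the monocyte marker CD14 was at -0.76 ± 0.13 and -0.71 ± 0.13.

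The cells with the non-silencing vector differed from the parental cells by less. Infection, vector and puromycin all differ between these groups and cannot be told apart. KRT19 was lower in shNS cells by -1.47 ± 0.10 on the log2 scale, GLDC, a glycine-cleaving enzyme, by -1.41 ± 0.23, and the ion channel TRPM4 by -1.20 ± 0.21. PADI4, a peptidylarginine deiminase, was higher by 1.51 ± 0.12, CRISPLD2 by 1.06 ± 0.15 and BEX1 by 1.04 ± 0.08. In total 872 genes passed, 378 higher and 494 lower, but only 6 and 8 changed at least 2-fold, and 3144 genes (25%) had non-overlapping arrays against the 10% of chance. Median scaling gave a median of all genes of -0.125, against -0.011 as reported, and 9.2% higher calls in place of 43.3%. Between 481 and 642 genes passed when 1 array was left out. Without shNS replicate 1 there were 521, without shNS replicate 3 481, and without parental replicates 2 and 3 535 and 559.

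Several lists that rose in the shRNA lines lay lower in shNS than in parental cells. Of 27 interferon-stimulated genes, 5 fell and 0 rose (8 and 0 adjusted over the list alone; median -0.27, adjusted p = 0.00019), among them BST2 at -0.38 ± 0.08. Of 15 basal genes, 7 fell and 0 rose (10 and 0 adjusted over the list alone; median -0.26, adjusted p = 0.00019), with KRT5 at -0.37 ± 0.08, and of 14 luminal genes, 4 fell and 0 rose (5 and 1 adjusted over the list alone; median -0.19, adjusted p = 0.00063), with MUC1 at -0.56 ± 0.09. Of 20 NF-kappaB and cytokine genes, 5 fell and 0 rose (6 and 0 adjusted over the list alone; median -0.11, adjusted p = 0.017), with BIRC3 at -0.64 ± 0.10. Lower medians also held for epithelial junction genes (-0.27, adjusted p = 0.00019, 5 of 20 fell, 7 adjusted over the list alone), proteases (-0.18, adjusted p = 0.0012, 5 of 19, 6 adjusted over the list alone), integrins (-0.17, adjusted p = 0.0023, 3 of 23, 6 adjusted over the list alone), ATF4 genes (-0.16, adjusted p = 3e-04, 4 of 22, 5 adjusted over the list alone) and mitosis genes (-0.15, adjusted p = 0.00022, 6 of 26, 9 adjusted over the list alone). In these lists 0 genes rose. Mesenchymal genes were higher (0.07, adjusted p = 0.017), as 3 of 13 rose and 0 fell, also when adjusted over the list alone, and SNAI2 rose by 0.58 ± 0.09. With median scaling the median turned to -0.07 and the call was lost (adjusted p = 0.08; 0.00069 to 0.08 over 12 settings). ERK pathway targets had a median of 0.00 (adjusted p = 0.63).

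Single genes were also set against the parental cells, a comparison added after seeing the data. Of the genes taken by the naming rule that passed against shNS, 85 of 99 in sh4 and 88 of 101 in shPld cells passed in the same direction. In sh4 cells 10 did not pass and 4 lay in the other direction without passing, and in shPld cells 12 and 1. The rule took mostly genes with large changes against shNS, so these shares need not hold for all calls. Of the 2299 genes changed the same way in both lines against shNS, 1569 also passed in that direction against parental cells in both lines. KRT19 was at 0.99 ± 0.10 in sh4 and 1.02 ± 0.10 in shPld cells, under 50% of its rise against shNS. PCNA was at -0.53 ± 0.09 and, without passing, at -0.21 ± 0.09, after a rise of 0.54 ± 0.09 in shNS cells. NDRG1, which fell by -0.86 ± 0.09 in shNS cells, did not pass (0.13 ± 0.09 and 0.21 ± 0.09). IL1A fell by -0.53 ± 0.07 in shNS cells, and its level in both lines lay below the parental cells without passing (-0.10 ± 0.07 and -0.13 ± 0.07). Nor did IFI27 (0.24 ± 0.26), EGFR (-0.16 ± 0.07), AURKB (-0.20 ± 0.08) or CENPF (0.22 ± 0.10) pass in sh4 cells, or MX1 (0.22 ± 0.18), ERBB2 (0.21 ± 0.11) or CCNB1 (0.25 ± 0.10) in shPld cells. IL6 passed in both lines (0.90 and 0.71), and HBEGF in sh4 cells (-0.68).

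The 2 shRNA lines differed from each other in few genes. COL8A1, a collagen chain, was lower in shPld than in sh4 cells by -1.35 ± 0.14, the planar polarity gene PRICKLE1 by -0.91 ± 0.08 and the zinc finger gene ZNF148 by -0.82 ± 0.11. FLNA, an actin crosslinker, was higher by 1.30 ± 0.23 and USP20, a deubiquitinase, by 1.27 ± 0.24, both above background on 1 of 3 sh4 arrays, and PTPN20 by 1.26 ± 0.23. In total 268 genes passed, 93 higher and 175 lower, 11 and 4 of them at least 2-fold, with 2514 genes (20%) non-overlapping against the 10% of chance. Median scaling gave a median of all genes of 0.125, against 0.002 as reported, and 86.8% higher calls in place of 34.7%. Of the 20 lists only the mitosis genes shifted in camera, with 5 of 26 lower and 0 higher (11 and 0 adjusted over the list alone; median -0.17, adjusted p = 3.3e-07), among them KIF20A at -0.38 ± 0.08. The KIF20A call was lost with median scaling (-0.24) and without sh4 replicate 1 (-0.35), shPld replicate 2 (-0.35) or shPld replicate 3 (-0.38), with an adjusted p of 0.01 to 0.41 over 12 settings. Without shPld replicates 1, 2 and 3 the count of genes was 117, 155 and 124, and without sh4 replicates 2 and 3 it was 137 and 126.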

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

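The direct comparison of the shRNA lines was planned before the data were examined, while all tests of explanations below, with their thresholds, were chosen after the results had been seen. A first version of the leukocyte test, on 9 leukocyte genes of the fixed marker list, was replaced by the one given here after the levels of PTPRC and CSF1R were known.

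A difference between the changes of the 2 lines was tested directly in limma, as shPld minus sh4 (log2, n = 3 arrays per group). It passed for 268 genes, and the mitosis genes shifted by a median of -0.17. Of the genes taken by the naming rule, higher in shPld cells were FLNA (1.30), USP20 (1.27), PTPN20 (1.26), LOC392221 (1.16, at least 1.52-fold), IFI27 (1.11), CCDC125 (1.07), PEX11A (1.07), LBP (1.04), HLA-DRA (0.50), CCL20 (0.45) and SOD2 (0.39). Lower were, among others, COL8A1 (-1.35), SRPK2 (-1.06), CRYBA2 (-1.03, at least 1.62-fold), LGALS12 (-1.01), GBGT1 (-0.99), PRICKLE1 (-0.91), CCDC15 (-0.86), ZNF148 (-0.82), FOXC1 (-0.57), NFKB1 (-0.51), CENPF (-0.40), KIF20A (-0.38), SLC7A5 (-0.38), AGO2 (-0.37), TPX2 (-0.36), NFKBIA (-0.31), CDC20 (-0.30) and THBS1 (-0.29). Of the 30 genes that the rule took and that passed, 7 kept their call in the 12 or fewer other settings in which they were tested, and 23 lost it in at least 1. Groups of 3 arrays are too small for a test of single arrays.

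Probes without a gene name took no part in the comparisons. Of the 1370 kept, 28 rose and 28 fell in both lines, and 6 of those that rose were above background on 0 of 3 shNS arrays.

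For each of the 4 comparisons the 6 arrays make 10 splits, and 1 of 10, the real one, gave as many genes or lists as the real one. These splits are too few for a share under 0.05. The real and the highest other count of genes were 3414 and 0 for sh4 minus shNS, 3242 and 0 for shPld minus shNS, 872 and 0 for shNS minus parental, and 268 and 0 for shPld minus sh4. For lists they were 8 and 5, 11 and 8, 10 and 2, and 1 and 0. Of 100 splits of the 9 arrays of sh4, shPld and shNS cells, 1, the real one, gave the full 2299 genes changed the same way. This does not exclude chance, because arrays of different lines are not exchangeable. A split that parts the shNS arrays mixes lines within its control, which lowers the count by design. Chance differences between the 3 lines are not covered either. The highest other count was 2209, from 1 of 3 splits that kept the shNS arrays together and exchanged arrays between the shRNA lines. The 96 splits that parted the shNS arrays gave at most 3.

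The common change of both shRNA lines was larger than the shared shNS arrays would give, since 1810 genes changed the same way with separate controls. Under 3 other normalizations at least 1761 did, but only median scaling replaced the quantile step. With median scaling 530 genes were higher and 1231 lower in both lines, against 1077 and 1222 as reported. Median scaling also moved the median of all genes down, to -0.175 in sh4 and -0.058 in shPld minus shNS, which favours lower calls. The 530 genes that were higher despite this shift argue against quantile normalization as the whole cause for them. The count of lower genes cannot decide this, since the shift adds to it. Lines drifting independently of each other would differ from each other about as widely as from shNS cells. In limma 268 genes passed between them, against 3414 and 3242 for sh4 and shPld minus shNS. With separate controls the lower correlation across genes was 0.68. A state common to parental and shNS cells would enter both changes and raise this correlation, so it does not show on which side the change arose. A loss of AREG was not tested as the cause, since AREG was not measurable. It stays open. Descent of both lines from 1 culture, effects of the shRNAs on other genes and a hairpin shared between the lines were not tested and stay open.

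The rise of some lists against shNS could come from a low level in the shNS line. Parental cells were the reference here, but they were uninfected and grown without puromycin, so they differ from the shRNA lines in this as well. For interferon-stimulated genes in sh4 cells a low shNS level remained a candidate explanation, with a median of 0.07 and a camera adjusted p of 0.13 against parental cells. In shPld cells it stays open, with a median of 0.16 and an adjusted p of 0.049, or 0.069 with an estimated correlation. A response to any hairpin vector would also raise the list in shNS cells, but the list was lower there than in parental cells (median -0.27). A low level particular to the shNS line would hide such a response, so a vector response stays open. In sh4 and shPld cells the adjusted p against parental cells were 4.7e-08 and 5.1e-06 for basal and 1.8e-05 and 3.8e-05 for luminal genes, with none above 0.0095 with an estimated correlation, which argues against a low shNS level as the whole cause. The same holds for NF-kappaB and cytokine genes in sh4 cells, where the median was 0.37 against parental and 0.40 against shNS cells (adjusted p of 0.0051 against parental, 0.023 with an estimated correlation). In shPld cells the median was 0.23 against parental and 0.39 against shNS cells, and the adjusted p was 0.027, but 0.054 with an estimated correlation. A low shNS level therefore stays open there. No biological explanation was tested for this pattern.

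Signal shared between HLA-DRB copies does not account for the fall of HLA class II genes, as 4 of 4 others (HLA-DRA, HLA-DMA, HLA-DMB and CD74) fell in both lines. Values against fewer leukocytes in the knockdown cultures as the cause came from 10 abundant leukocyte transcripts. Of these, 2 (ITGB2 and LYZ) were above background on all 6 control arrays, and PTPRC, CSF1R, TYROBP, FCER1G, LAPTM5 and CD53 on 0 of 6, AIF1 on 2 of 6 and SPI1 on 1 of 6. ITGB2 was at -0.45 in sh4 and -0.61 in shPld cells, and LYZ, which did not pass, at 0.40 and 0.25. The monocyte marker CD14, above background on all 12 arrays, was at -0.76 and -0.71. The samples were cultures of a carcinoma cell line, so its signal need not come from monocytes. The transcripts at 0 of 6 argue against many leukocytes in the control cultures, although PTPRC and CSF1R were known before the 10 were chosen. The share of leukocytes that would carry HLA-DRA was not computed. No biological explanation was tested for the fall.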

How the results depend on the processing

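The alternatives were planned before the data were examined, except normexp with an offset of 50 and the parental cells as control for gene lists and named genes, which were chosen after seeing the data. Values here cover the counts, the named genes and lists past the threshold in a comparison, and for the lines against shNS all lists and the always-named genes. Other genes named for 1 line are not covered in the line where they did not pass. This coverage was set after changes of direction had been seen. For 100 other results, none past the threshold, 97 of 1308 values changed direction, 0 of those past the threshold. Of the covered single genes and lists, 4465 values kept direction and side of the threshold, 407 lost their call, 22 gained one and 27 changed direction. These totals count the authors' values and no background correction separately, although both hold the same values. Direction is the sign of the log2 fold change for a gene, and for a list that of camera's test, which can differ from the sign of its median. With median scaling these were CXCL8 (-0.04) and hypoxia genes (-0.19) in sh4 cells and proteases (-0.18) in shPld cells. Proteases in shPld cells also turned with the strict filter (0.04), the replicate block (-0.18), and without shPld replicate 2 (-0.17), shPld replicate 3 (-0.17), shNS replicate 2 (-0.20) and shNS replicate 3 (-0.12), the range with 1 array left out being -0.20 to -0.09. With parental cells as control, proteases (-0.06), junction (-0.23), hypoxia (-0.21) and microRNA genes (-0.01) turned in sh4 cells, and integrins (-0.06), junction (-0.22), hypoxia (-0.12) and microRNA genes (-0.03) in shPld cells. None of these was past the threshold in either setting. Covered single genes that changed direction with parental cells as control were ADAM17 (-0.07), AGO2 (-0.11), ATF5 (-0.21), ATXN2 (-0.05), IL1A (-0.10), IL1B (-0.10) and ITPRIPL2 (-0.19) in sh4 cells and IL1A (-0.13), IL1B (-0.13) and SERPINA3 (-0.46) in shPld cells. All but IL1B had passed against shNS, and SERPINA3 passed against parental cells as well. Of the named genes that are not covered, PECAM1 (-0.08) and PRKRA (-0.01) turned in sh4 cells. In shPld cells ADAM17 (-0.17), CENPF (-0.18) and TNRC6A (0.00) did. These passed neither against shNS nor against parental cells. The medians given are those in the changed setting. Their sign differed from the median as reported only for proteases with the strict filter (-0.18 as reported) and, with parental cells as control, for junction genes in both lines (0.10 and 0.06), microRNA genes in sh4 cells (0.16) and integrins in shPld cells (0.01). CXCL8 went from 0.18 to -0.04, and microRNA genes in shPld cells from 0.00 to -0.03. In the others only the test's direction turned. The cause was not tested.

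Counts for shNS minus parental and shPld minus sh4 were 382 and 76 with median scaling, 576 and 150 without a filter and 211 and 28 without the trend, and the cause was not tested. Stricter thresholds lowered counts by construction. With at least 2-fold they were 481 for sh4 minus shNS, 482 for shPld minus shNS, 347 for both lines, 14 for shNS minus parental and 15 for shPld minus sh4. At an adjusted p under 0.01 they were 2229, 2141, 1513, 335 and 78. In sh4 minus shNS, 13 lists shifted without a filter and 17 with fry, which does not compare a list with other genes, and 2 did with fry in shPld minus sh4. Median scaling kept 71.7%, 68.6%, 37.8% and 25% of the calls of the 4 comparisons, the other normalizations 96.3% to 99.1%. With the replicate number as a block, 3454, 3316, 897 and 304 genes passed and 2341 in both lines.

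With 1 array left out, the count lay between 2821 and 3042 for sh4 minus shNS, between 2717 and 2800 for shPld minus shNS, and between 1903 and 2100 for both lines. For shNS minus parental it lay between 481 and 642, with 521 and 481 without shNS replicates 1 and 3 and 535 and 559 without parental replicates 2 and 3. For shPld minus sh4 it lay between 117 and 235, with 117, 155 and 124 without shPld replicates 1, 2 and 3 and 137 and 126 without sh4 replicates 2 and 3. Lists past the threshold numbered 8 to 9, 10 to 11, 10 to 11 and 1. The log2 difference of the AREG probe lay between -0.13 and 0.05 in sh4 and between -0.11 and 0.02 in shPld cells. The probe was at background, so these values do not measure a change of AREG. A chip block was not run, as no chip is named. Signal near background limits what could be measured, as 37.5% to 41.6% of probes were above it.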

Other observations

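The tests here, on 17 gene families formed by symbol, were all chosen after the results had been seen, as was the replication minus mitosis level.

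Histone genes were higher in both shRNA lines than in shNS cells: of 31 measured, 17 rose and 1 fell in sh4 cells and 15 rose and 2 fell in shPld cells (medians 0.72 and 0.51, camera adjusted p of 9.3e-08 and 7.9e-08, with an estimated correlation 0.0093 and 0.0091). With median scaling the medians were 0.58 and 0.47. H2AC6 rose by 2.24 and 2.33 and H2BC5 by 1.99 and 1.90. Several histone genes have near-identical copies, so these are not separate measurements. Of 7 metallothioneins, 5 rose and 0 fell in each line (medians 0.36 and 0.42, adjusted p of 0.0011 and 0.00043), with MT1X up by 0.99 and 1.08, and with median scaling the medians were 0.20 and 0.41. In shNS against parental cells 3 metallothioneins fell and 0 rose (median -0.26, adjusted p of 0.0014).

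The mean replication minus mean mitosis level (log2) was -1.04 ± 0.03 in parental, -0.83 ± 0.06 in shNS, -1.29 ± 0.05 in sh4 and -1.19 ± 0.03 in shPld cells (SD, n = 3 each). A permutation test of the arrays was run and dropped, because the 12 arrays come from 4 lines and are not exchangeable. Whether fewer cells were in S phase was not measured.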
